A study of Homo sapiens with 6 samples.

How the data were processed

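Total RNA of 6 samples of human adult adrenal cells in primary culture was copied into biotin-labelled cRNA and read on 6 arrays of a single Illumina bead chip, 1 array per sample. Per the labels, 3 samples were untreated controls and 3 were treated with ACTH, and the treatment lasted 48 h. The labels number the groups and not the samples, so replicates are numbered here in the order of the deposited samples. Nothing in the labels says whether the 3 samples of a group were separate cultures, so the p-values measure only the spread between these samples, which may be partly technical.

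The authors read the chip with GenomeStudio, per the labels, which give neither a version nor settings. The deposited table of probe signals holds bead intensity on a linear scale, neither normalized between arrays nor background-subtracted, for 48803 probes. The deposited detection values are called a p-value (Detection Pval) in the header, but 19.9% of them were exactly 1, the value of probes brighter than all negative controls if they run as 1 minus p, and they were read that way. They stood in another row order than the signals: the rank correlation of signal and detection value in the same row lay between 0.000787 and 0.00494 across the 6 arrays. Detection values were therefore paired with signals by rank within each array. After this pairing, the 6 values of a deposited row lay a median distance of 0.00224 from the nearest paired row, against at least 0.0504 when 2 arrays were exchanged.

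The authors' processed values, deposited as a separate table, are on a log2 scale. Setting differences between arrays against those of the signals showed that each value was the log2 signal minus the 75th percentile of its array and minus a centre per probe. The set of arrays behind that centre stays unknown. The direction was that of the signals. The medians of the 6 columns were -0.08, -0.01 and -0.18 for the control arrays and -0.30, -0.19 and -0.20 for the ACTH arrays. The same differences matched the rows of both tables one to one (48803 rows, 48603 of them within 0.0001 on the log2 scale, the largest distance 0.0111). This match gave the signals their probe identifiers. Of these probes, 28098 had 1 gene symbol in the platform annotation, 13 had several and 20692 were unnamed there. Of the named probes, 28059 were found by gene identifier in a RefSeq table of assembly GRCh38.p14, and no symbol needed an update. No genomic positions are given, because the array tables name no genome build. Some genes were left out of every table, with 122 probes in all, and are not analysed here.

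Signals were background-corrected with the normexp model of limma 3.58.1 in R 4.3.3, with the negative-control mean and SD inferred from the detection p-values and an offset of 16, then quantile-normalized between arrays and log2-transformed. Probes with a detection p below 0.05 on at least 3 of the 6 arrays were kept, whatever their group. Probes with 1 gene symbol were kept (15845), and a gene with several was represented by the probe with the highest mean signal, which left 12021 genes. Tables were read and drawn with Python 3.11.15, the R package data.table (1.17.8), numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

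The median signal per array lay between 64.3 and 71.5 units, and 17503 to 19586 probes per array were detected. A gene not detected on any array of 1 group has only a lower bound of its fold change. That bound sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own value and the lowest value among detected probes. The precision of every value is limited by the number of arrays, 3 per group.

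ACTH was compared with control by a linear model on log2 values (lmFit and eBayes in limma) over all 6 arrays, without a block, and two-sided p-values were adjusted by the Benjamini-Hochberg method over all genes. The threshold was an adjusted p below 0.05, and genes with a difference of at least 2-fold were counted separately. Before the data were examined, 36 gene lists were fixed: pathways of steroid, lipid and stress biology, and markers of the cell types that an adrenal culture could hold. Of these, 33 had at least 5 measured genes and were tested with camera in limma at a preset correlation between genes of 0.01, against all other genes, with Benjamini-Hochberg adjustment over the 33 lists. Camera with the correlation estimated from the data, and fry, were run beside it. Fry tests whether the genes of a list move, on balance, one way, and does not compare them with other genes.

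The chip carried the 6 arrays at positions 7 to 12, with 1 control and 1 ACTH array at positions 7 and 8 (replicate 1 of each group), 9 and 10 (replicate 2), and 11 and 12 (replicate 3). Deviations from the group means, over the 12021 genes, correlated at 0.762, 0.766 and 0.637 within these pairs of neighbouring positions, and between -0.674 and 0.0156 in the other control and ACTH pairs. A fit with the 3 pairs as a block was therefore added. It was chosen after these correlations had been seen and before its calls were counted, and no label says that neighbouring arrays share a culture. Its median residual SD was 0.154, against 0.267 without the block.

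The fixed rule for named genes had 3 parts. The first took the 12 largest differences in each direction among genes past the threshold whose groups did not overlap and that were detected on all arrays of the higher group. It gave no gene without the block, and was applied to the fit with the block instead, a choice made after the data were seen. The second took up to 4 measured members of each list with the smallest p, and the third 10 genes of the ACTH receptor and of steroid synthesis, of which 9 were measured and 1 is not analysed here. Only part of the genes that the rule allows are named.

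The code was tested on simulated data with the gene levels, pair differences and spread of the fit with the block, less its ACTH differences. They held 12021 genes, with 100 genes changed at each of 2 sizes, over 15 simulations. The pairs were thus built in, and noise was drawn independently for each gene. With each gene's spread drawn from the fitted distribution, the fit without the block recovered a mean of 1.60 of 100 genes changed by 1 on the log2 scale and 65.6 of 100 changed by 2, with 0.133 false calls per simulation. The fit with the block recovered 77.6 and 99.1, and 5.44% of its calls were false. With each gene's own estimated spread, the fit with the block recovered 97.9 and 100 and 9.73% of its calls were false, above the nominal rate.

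Alternatives were run 1 at a time. They covered the background correction (none, or normexp with an offset of 50), the normalization between arrays (median scaling, cyclic loess or none), and the filter on dim probes (detected on all 6 arrays, a detection p below 0.01, or no filter). They also covered several probes of a gene (mean, or every probe alone), the variance model (intensity trend with a robust prior), array weights, the chip position as a numeric covariate, the authors' processed values, thresholds, set tests, and each replicate left out in turn. Other splits of the 6 arrays into groups of 3 were tested with the same fits. All 6 arrays lay on 1 chip, so no comparison between chips was needed, and no scan dates were used.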

Results

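Gene expression was measured in human adult adrenal cells in primary culture, which are cells taken from tissue and not an established line. The cells were left untreated (control) or treated for 48 h with ACTH, adrenocorticotropic hormone, the pituitary hormone that stimulates the adrenal cortex to make cortisol. Each group held 3 samples, and each sample was read on 1 bead array with 48803 probes. The mean signal per array was between 351 and 501 intensity units, and 35.9% to 40.1% of the probes of an array were detected above its negative controls. After normalization, the correlation between arrays of a group, across 12021 genes, which are not independent replicates, was 0.931 to 0.974 in controls and 0.940 to 0.976 with ACTH.

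The comparison of ACTH with control asked which genes differ in expression after 48 h of the hormone. The ACTH receptor MC2R, its accessory protein MRAP, the cholesterol carrier STAR and enzymes of cortisol synthesis were higher with ACTH, several of them by more than 10-fold in the mean. Genes of cholesterol synthesis, fatty acid synthesis and the metallothioneins rose together, and genes of the cell cycle fell together, as gene lists tested against all other genes with a preset correlation. These calls were lost with a correlation estimated from these arrays (adjusted p = 0.2075 for the first 3 lists and 0.512 for the cell cycle), and no list passed with fry (lowest adjusted p = 0.118). No single gene passed the threshold in the planned fit (0 of 12021 genes, limma, smallest adjusted p = 0.102 for INHA), and 484 genes had an unadjusted p below 0.05 where chance gives 601. The groups did not overlap in 565 genes that were higher and 529 that were lower with ACTH, together 9.10% of the genes, where chance gives 10%. Both chance values hold for independent arrays. Neighbouring control and ACTH arrays deviated together, which lowers what chance gives here, so neither count shows fewer differences than chance.

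Arrays at neighbouring chip positions, 1 control and 1 ACTH array in each of 3 pairs, deviated together from their group means. With these pairs as a block, 157 genes passed (limma, Benjamini-Hochberg), of which 119 were higher and 38 lower with ACTH, and 126 differed by at least 2-fold (98 higher, 28 lower). In this fit 1893 of the 12021 genes had an unadjusted p below 0.05. Simulations of this fit built in the pairs and drew the noise of each gene independently. In them 5.44% to 9.73% of the calls were false, depending on the spread assumed. They do not test whether the pairing is real, and give no error rate for the 157 calls. The count of 157 rested on single pairs: it was 6 without the third pair, 381 without the second and 230 without the first. The 6 genes left without the third pair were INHA, MC2R, CYP17A1, AMDHD1, MT1G and MRAP, which kept the call in every setting with the block. Each other gene named below as passing with the block lost its call in 1 to 5 of 13 to 15 such settings.

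**Figure D1:**
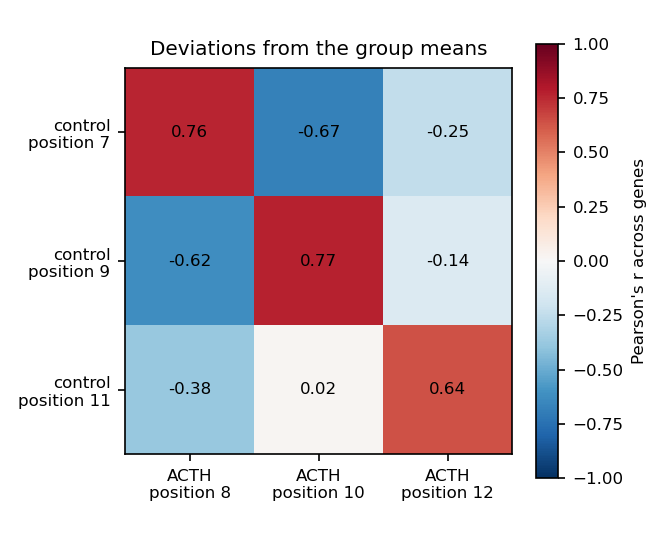
Correlation, across 12021 genes, of the deviations from the group means between each control array (one axis) and each ACTH array (the other axis), labelled by chip position. The 3 pairs of neighbouring positions have correlations of 0.762, 0.766 and 0.637, and the other pairs lie between -0.674 and 0.0156.

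The 9 measured genes fixed in advance were all higher with ACTH in the mean. None passed in the planned fit, and 7 passed with the neighbouring positions as a block. Each SE here and below is from the planned fit, also beside an adjusted p of the fit with the block. Where an SE with the block is given, it is named as such. CYP17A1 (probe ILMN_1760554), the steroid hydroxylase needed for cortisol and adrenal androgens, had a normalized log2 signal of 12.34 ± 1.08 (SD, n = 3) with ACTH and 6.99 ± 1.60 in control. The difference was 5.35 on the log2 scale (SE 0.88, and 0.20 with the block, adjusted p = 0.000179 with the block). MC2R (ILMN_1778521) had 9.95 ± 0.76 with ACTH and 5.68 ± 0.83 in control, where it was detected on 2 of 3 arrays, a difference of 4.28 (SE 0.52, and 0.13 with the block, adjusted p = 7.34e-05 with the block). MRAP (ILMN_1705676), which carries the receptor to the cell surface, differed by 4.03 (SE 0.82, adjusted p = 0.000846 with the block), and a further probe gave the same value. STAR (ILMN_1689702), which delivers cholesterol into mitochondria, had 12.62 ± 1.15 with ACTH and 8.68 ± 2.04 in control, a difference of 3.94 (SE 1.06, adjusted p = 0.00450 with the block).

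CYP11A1 (ILMN_1768820), which cuts the cholesterol side chain, was already bright in control at 12.15 ± 1.36 and reached 14.27 ± 0.68 with ACTH (difference 2.13, SE 0.70, adjusted p = 0.0221 with the block). HSD3B2 (ILMN_1733462) differed by 3.47 (SE 1.15, adjusted p = 0.00705 with the block). CYP11B1 (ILMN_2358436), the enzyme of the last step to cortisol, differed by 4.82 (SE 1.42, adjusted p = 0.0452 with the block), with 1.99, 5.71 and 6.75 in the 3 pairs. CYP21A2 (ILMN_1773082) differed by 3.56 (SE 1.08) and NR5A1 (ILMN_1815320), the transcription factor of steroid-producing cells, by 1.21 (SE 1.13). The value of NR5A1 depended strongly on single arrays and lay between 0.25 and 2.34 over the settings of the planned fit. For other genes that moved strongly when 1 array was left out, this range over the settings is given below. Neither of the 2 genes passed with the block, at adjusted p = 0.0658 and 0.0990, though they passed in 7 and 5 of 15 other settings with it. Probes of CYP11B1, CYP21A2 and HSD3B2 may also bind the transcripts of their close copies CYP11B2, the CYP21A2 pseudogene and HSD3B1, since the files give no probe sequences.

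**Figure D2:**
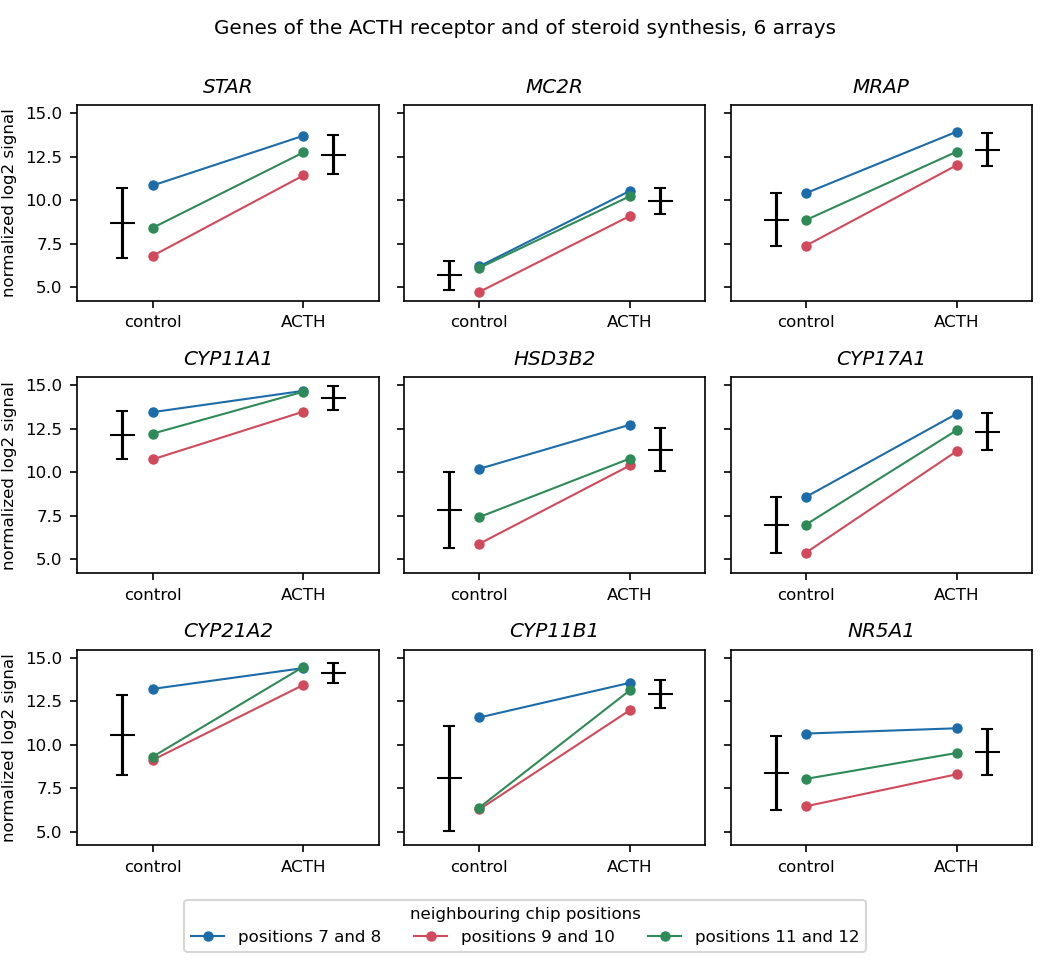
Normalized log2 signal of 9 genes fixed in advance, in control and ACTH arrays. Coloured points are single arrays, lines join arrays at neighbouring chip positions, and black bars give the mean and SD of 3 arrays. In all 3 pairs each gene is higher with ACTH, and the lines of CYP11B1 differ most in slope, from 1.99 to 6.75.

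Beyond these genes, the largest differences among genes that passed with the block included INHA, the inhibin alpha subunit, at 4.64 (SE 0.37, and 0.15 with the block, adjusted p = 7.34e-05 with the block), detected on 2 of 3 control arrays. The retinol dehydrogenase RDH12 was higher by 3.85 (SE 0.69), AMDHD1, an enzyme of histidine breakdown, by 3.32 (SE 0.79), the semaphorin SEMA6D by 2.84 (SE 0.82) and the kinase MAPK4 by 2.77 (SE 0.97). RDH12 and SEMA6D were detected on 1 of 3 control arrays and MAPK4 on 2. ATP4A, a proton pump subunit, was not detected on any control array and was at least 7.66-fold higher with ACTH. Of the genes that were lower, HOPX, a transcriptional cofactor, differed by -2.87 (SE 0.55), the serotonin receptor HTR2B by -2.47 (SE 0.45) and the fatty acid transporter SLC27A2 by -1.95 (SE 0.36). AKAP19 differed by -1.89 (SE 0.36), the matricellular protein CCN5 by -1.78 (SE 0.29), the carboxypeptidase CPA4 by -1.69 (SE 0.58) and the complement component C3 by -1.58 (SE 0.25). The aldo-keto reductases AKR1B10 and AKR1B15, whose close sequences may share signal, differed by -1.43 (SE 0.45) and -1.31 (SE 0.38), and BABAM2 by -1.22 (SE 0.34). RRAD and TMEM229A were not detected on any ACTH array and were at least 2.06-fold and at least 2.20-fold lower. With the block, the adjusted p of the genes in this paragraph lay between 7.34e-05 for INHA and 0.0490 for AKR1B10. Without the third pair, of the genes in this paragraph only INHA and AMDHD1 passed with the block.

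Of 33 gene lists tested, 14 passed camera with a preset correlation (11 higher, 3 lower with ACTH). None passed with a correlation estimated from these arrays (lowest adjusted p = 0.2075) or with fry (lowest adjusted p = 0.118). A higher correlation does not account for the loss of every list. The estimate was below the preset 0.01 for cholesterol uptake, storage and transport (-0.029), steroidogenic transcription regulators (-0.078) and adipocyte markers (-0.126). Camera with an estimated correlation also rests on the residual degrees of freedom of the fit, 4 here, which limits what it can call. Of the 10 ways to split the 6 arrays into groups of 3, 4 gave at least 14 lists, the real split included, and the highest of the others gave 19. Apart from the real one, these splits kept both arrays of a neighbouring pair in the same group. The other splits that part all 3 pairs, as the real one does, gave 2, 4 and 4 lists. The counts of passing members below are over all genes in the fit with the block, since 0 members of any list passed without it.

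The steroid synthesis enzymes rose together: all 10 measured genes were higher, with a median of 2.99 and pair medians of 1.61, 3.53 and 3.13 (camera adjusted p = 6.24e-13, and adjusted p = 0.2075 with an estimated correlation). Adjusted over the list alone, 7 of the 10 passed without the block. With the block 7 passed over all genes and 10 adjusted over the list alone. FDX1, which carries electrons to the mitochondrial steroid enzymes, was higher by 2.52 (SE 0.54) and passed with the block. The adrenocortical cell markers, all 13 of which are also in other lists, rose with a median of 3.56 (camera adjusted p = 2.12e-19, and adjusted p = 0.2075 with an estimated correlation). Of these, 12 were higher and 10 passed with the block. Adjusted over the list alone, 11 passed without the block. SULT2A1, which sulphates adrenal androgens, differed by -0.24 (SE 0.82), and its direction turned in 5 of 20 settings (range -0.74 to 0.68), among them without normalization between arrays (0.10).

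Genes of cholesterol synthesis rose with a median of 1.42 over 19 measured genes, and by 2.06, 0.52 and 1.45 in the 3 pairs (camera adjusted p = 1.75e-22, and adjusted p = 0.2075 with an estimated correlation). Of the 19, 17 were higher, 3 passed with the block, and 15 passed without it adjusted over the list alone. IDI1 was higher by 2.12 (SE 0.36), FDPS by 1.74 (SE 0.32) and EBP by 2.54 (SE 0.52), which passed with the block. MVD was higher by 2.19 (SE 0.49) and did not pass with the block, though it passed in 8 of 15 other settings with it. Genes of fatty acid synthesis and desaturation rose with a median of 0.76, and all 15 were higher (camera adjusted p = 3.82e-15, and adjusted p = 0.2075 with an estimated correlation). Of these, 2 passed with the block, and 9 passed without it adjusted over the list alone. ACSL1, which activates long-chain fatty acids, was higher by 1.77 (SE 0.31) and passed with the block, as did GPAM (0.76), named after its value was seen. SCD and FADS1, both fatty acid desaturases, were higher by 1.17 (SE 0.24) and 1.48 (SE 0.36) and did not pass with the block, though they passed in 7 and 5 of 15 other settings with it.

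Cholesterol uptake, storage and transport genes had a median of only 0.11 over 17 genes, 10 of them higher (camera adjusted p = 0.0222, and adjusted p = 0.2075 with an estimated correlation). Of these, 4 passed with the block, among them the lipoprotein receptor SCARB1 (2.22, SE 0.79), the hormone-sensitive lipase LIPE (2.30, SE 0.59) and the lysosomal cholesterol transporter NPC1 (0.88, SE 0.16). The cholesterol esterifying enzyme SOAT1 (0.95, range 0.41 to 1.40), named after its value was seen, was the remaining one. STARD4 was higher by 1.15 (SE 0.31) and did not pass, though it passed in 4 of 15 other settings with the block. Adjusted over the list alone, 3 passed without the block. The median of this list was 0.18 without ACTH replicate 1 and 0.06 without ACTH replicate 2, and 0.43 without normalization between arrays. Its call was lost without control replicate 2 (adjusted p = 0.114), without ACTH replicate 2 (adjusted p = 0.0605) and with array weights (adjusted p = 0.0654).

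Metallothioneins, small metal-binding proteins, rose with a median of 1.50, and all 8 were higher (camera adjusted p = 2.01e-09, and adjusted p = 0.2075 with an estimated correlation). Of these, 4 passed with the block, and 2 passed without it adjusted over the list alone. MT1G was higher by 2.55 (SE 0.45), MT1H by 1.96 (SE 0.53) and MT1E by 0.85 (SE 0.35), and these passed with the block, as did MT2A (1.35, range 0.77 to 1.85), named after its value was seen. MT1F was higher by 1.65 (SE 0.65, range 1.07 to 2.37) and did not pass with the block, though it passed in 10 of 15 other settings with it. Leaving out single arrays, the median of the list lay between 0.98 and 2.11 and the call was kept. Members of this family are close in sequence and their probes may share signal. Glucocorticoid-response genes rose with a median of 0.40, 16 of 17 being higher (camera adjusted p = 5.37e-05, and adjusted p = 0.2075 with an estimated correlation). Of these, 2 passed with the block, and 0 without it adjusted over the list alone. The median lay between 0.26 and 0.63 when single arrays were left out and was 0.73 without normalization between arrays, and the call was kept. TSC22D3 was higher by 1.12 (SE 0.25) and passed with the block, as did PDK4 (1.50, range 0.76 to 2.21), named after its value was seen. SGK1, FKBP5 and MAOA were higher by 0.61 (SE 0.24), 0.70 (SE 0.30, range 0.42 to 1.04) and 0.95 (SE 0.44, range 0.41 to 1.29) and did not pass.

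The list of ACTH receptor and cAMP signalling genes had a median of 0.10 over 21 genes (camera adjusted p = 0.0170, and adjusted p = 0.2075 with an estimated correlation), and its 2 members that passed with the block were MC2R and MRAP. The steroidogenic transcription regulators had a median of 0.16 over 12 genes, 11 of them higher and 0 past the threshold (camera adjusted p = 0.0360, and adjusted p = 0.2075 with an estimated correlation). NR5A2 was higher by 0.45 (SE 0.22, range 0.23 to 0.75). The cAMP-responsive early genes had a median of 0.31 over 15 genes, 9 of them higher and 0 past the threshold (camera adjusted p = 0.0320, and adjusted p = 0.512 with an estimated correlation). SIK1, a kinase, differed by 1.44 (SE 0.41), KLF4 by 0.81 (SE 0.30, range 0.37 to 1.13), FOS by 0.64 (SE 0.30) and CREM by 0.48 (SE 0.18). SIK1 passed in 4 of 15 other settings with the block. The median of the receptor list was 0.06 without control replicate 2 and 0.18 without control replicate 3, and that of the early genes 0.11 without control replicate 2 and 0.15 without ACTH replicate 1. The early genes were lost with the block (adjusted p = 0.0578). All 3 calls were lost in several other settings, with values in the order given. Without normalization between arrays the medians were 0.37, 0.49 and 0.50 and the adjusted p was 0.0772, 0.0833 and 0.239, and with chip position as a covariate it was 0.0530, 0.0638 and 0.175. Without control replicate 2 the adjusted p was 0.127, 0.114 and 0.146, and without ACTH replicate 3 it was 0.0578, 0.111 and 0.177. The regulators and the early genes were also lost without control replicate 1 (0.0632 and 0.0604), the regulators without ACTH replicate 2 (0.0628) and the early genes without ACTH replicate 1 (0.115). The receptor list was also lost with array weights (0.0548) and with the authors' values (0.0730), the regulators with the mean of a gene's probes (0.0771), and the early genes with median scaling (0.0743), array weights (0.0920) and the authors' values (0.0730).

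Cell cycle genes fell together, with a median of -0.50 and pair medians of -0.64, -0.43 and -0.49 (camera adjusted p = 8.09e-10, and adjusted p = 0.512 with an estimated correlation). The median was -0.25 without control replicate 1 and -0.32 without ACTH replicate 2, and -0.18 without normalization between arrays, where the median of all genes was 0.27, and the call was kept. Of the 29 measured, 28 were lower and 1 passed with the block (CDC20, -0.74, range -1.06 to -0.39, named after its value was seen), which lost that call in 5 of 15 settings (highest adjusted p = 0.340). Adjusted over the list alone, 0 passed without the block and 23 with it. The replication helicase subunit MCM5 differed by -0.69 (SE 0.32, range -0.92 to -0.38), the kinetochore protein ZWINT by -0.69 (SE 0.32, range -0.92 to -0.39), the topoisomerase TOP2A by -0.59 (SE 0.28, range -0.78 to -0.27) and CENPF by -0.69 (SE 0.34, range -0.96 to -0.34). None of these 4 passed, though MCM5, ZWINT and TOP2A passed in 7, 2 and 1 of 15 other settings with the block. Zona glomerulosa genes, typical of the aldosterone-producing layer, fell with a median of -0.53, 11 of 13 being lower (camera adjusted p = 0.0222, and adjusted p = 0.512 with an estimated correlation). Without normalization between arrays the median was -0.19. The transcription factor LEF1 (-1.32, SE 0.85, range -2.07 to -0.59) and the signalling regulator RGS4 (-0.86, SE 0.51, range -1.26 to -0.42) passed with the block, and DAB2 (-0.61, SE 0.19) and the potassium channel KCNJ5 (-0.90, SE 0.61, range -1.44 to -0.20, detected on 2 control arrays and 1 ACTH array) did not. The calls of LEF1 and RGS4 with the block were lost in 2 and 3 of 15 settings, with the highest adjusted p, 0.228 and 0.319, without the third pair. This list was lost without control replicate 1 (median -0.05, adjusted p = 0.621), without ACTH replicate 2 (median -0.11, adjusted p = 0.210), with array weights (adjusted p = 0.203) and with chip position as a covariate (adjusted p = 0.124). Without control replicate 2 its median moved the other way, to -0.86, and the call was kept (camera adjusted p = 0.000119).

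Interferon-response genes fell with a median of -0.21, 17 of 18 being lower and 0 past the threshold (camera adjusted p = 0.00112, and adjusted p = 0.240 with an estimated correlation). Their pair medians were -0.41, 0.08 and -0.40, and without normalization between arrays the median was 0.09, where the median of all genes was 0.27 (-0.02 with normalization). Leaving out single arrays, the median lay between -0.40 and -0.19. IFIT3 differed by -0.67 (SE 0.18), RSAD2 by -0.76 (SE 0.36, range -1.17 to -0.43) and IFIT1 by -0.61 (SE 0.26). IFIT3 passed in 5 of 15 other settings with the block, and 1 of 3 probes of IFIT3 pointed the other way. Adipocyte markers had a median of 0.39, all 6 being higher and 0 past the threshold (camera adjusted p = 0.00766, and adjusted p = 0.2075 with an estimated correlation). The median was 0.67 without normalization between arrays. CIDEC, which coats lipid droplets, differed by 0.91 (SE 0.33, range 0.46 to 1.25) and lipoprotein lipase LPL by 0.37 (SE 0.19, range 0.17 to 0.64).

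**Figure D3:**
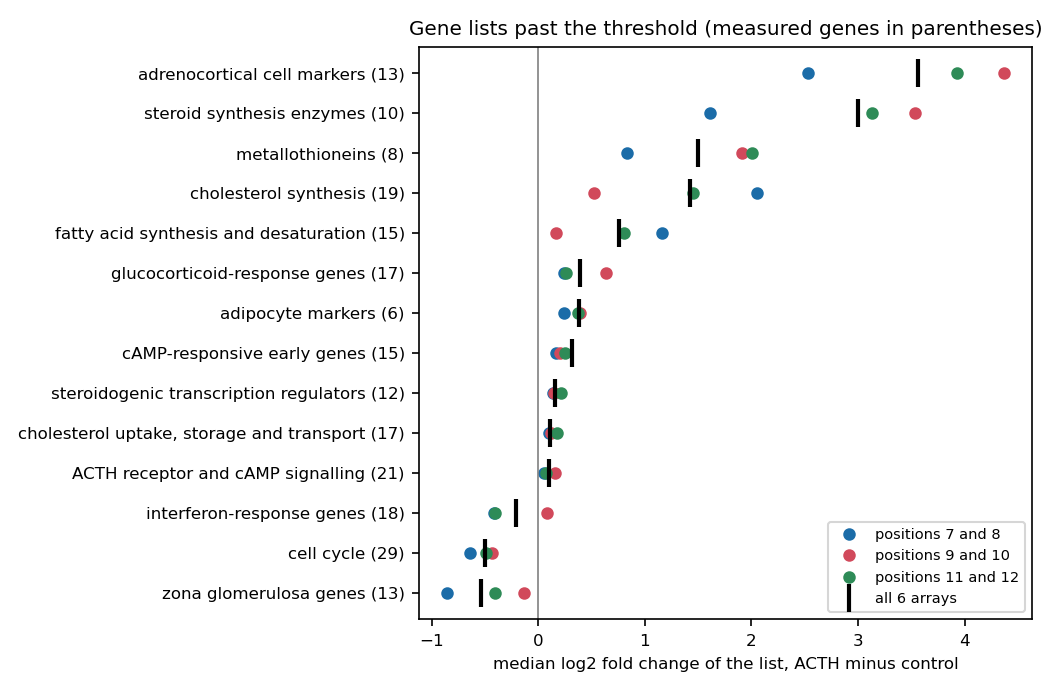
Median log2 fold change (ACTH minus control) of the 14 gene lists that passed camera with a preset correlation, with the number of measured genes in parentheses. Points are the medians within each pair of neighbouring chip positions, and the black tick is the median over all 6 arrays. The medians run from -0.53 for zona glomerulosa genes to 3.56 for adrenocortical cell markers, and that of the interferon-response genes, -0.21 here, is 0.09 without normalization between arrays.

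Among markers of other cell types, the median was -0.10 for chromaffin cells (camera adjusted p = 0.839), -0.17 for fibroblasts (0.348), 0.09 for endothelial cells (0.322), -0.14 for macrophages and monocytes (0.662), -0.06 for smooth muscle and pericytes (0.583) and -0.02 for epithelial cells (0.672). The adrenal capsule markers had a median of 0.07 and a mean of -0.03 (adjusted p = 0.974). The macrophage list had a mean of 0.02, opposite to its median. The scavenger receptor CD163, which was higher by 1.30 (SE 0.42), passed with the block, whereas CD14 differed by -0.53 (SE 0.28, range -0.73 to -0.19) and did not. The fibroblast list passed with the block (adjusted p = 0.0228, and adjusted p = 0.400 with an estimated correlation), and its median was 0.11 without normalization between arrays. S100A4, a fibroblast marker, differed by -0.58 (SE 0.22) and did not pass, though it passed in 4 of 15 other settings with the block. Lymphocyte, Schwann cell and neural, and erythroid markers had 4, 3 and 1 measured genes and were not tested.

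The other pathway lists did not pass in the planned fit. The closest were matrix proteases and inhibitors (median -0.33, camera adjusted p = 0.0504), heat shock and unfolded protein response (0.12, 0.0889) and adrenal androgen synthesis (0.23, 0.127). In the protease list MMP9 (-1.02, SE 0.38) passed with the block and CTSL (-0.44, SE 0.16) did not. In the androgen list AKR1C3 differed by -0.90 (SE 0.29) and did not pass. The median was -0.15 for growth factors and binding proteins (adjusted p = 0.449), whose mean was 0.08. In it FGF9 (2.21, SE 0.79, range 1.34 to 2.91) and INHA were higher and the activin antagonist FST (-0.90, SE 0.34) was lower, passing with the block, and TGFB2 (-0.81, SE 0.26) did not pass. The median was 0.02 for antioxidant enzymes (adjusted p = 0.637). In it the glutathione transferases GSTA4 (2.04, SE 0.55) and GSTA3 (2.54, SE 1.19, range 1.63 to 3.64, detected on 2 of 3 control arrays) passed with the block, and SOD2 (-0.77, SE 0.26), which passed in 7 of 15 other settings with it, and NQO1 (-0.34, SE 0.17) did not. The GSTA genes are close in sequence.

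Medians were -0.11 for extracellular matrix (adjusted p = 0.666), -0.10 for TGF-beta and YAP target genes (0.574), -0.15 for actin cytoskeleton and contractile genes (0.453), -0.10 for chemokines and cytokines (0.872), 0.02 for glycolysis and hypoxia genes (0.939) and -0.04 for ribosomal proteins (0.453). Oxidative phosphorylation had a median of -0.02 and a mean of 0.02, with the test pointing upward (adjusted p = 0.780). With the block, 16 lists passed, 13 of them among the 14 above. The further lists were matrix proteases and inhibitors (adjusted p = 0.0147), actin cytoskeleton and contractile genes (0.0435) and fibroblast markers (0.0228), all lower, and the actin list had a median of 0.13 without normalization. Each was lost without a single pair: the proteases without the second (0.0647), the actin list without the second (0.0856) or the third (0.166) and the fibroblast list without the first (0.0987) or the third (0.112). The fibroblast and actin lists were also lost with the block and median scaling (0.130 and 0.155), no normalization (0.130 and 0.155) or the authors' values (0.0559 and 0.05001), and the actin list with the mean of a gene's probes (0.0687). None of the 16 passed with an estimated correlation (lowest adjusted p = 0.400) or with fry (0.0555). The fit with the block leaves 2 residual degrees of freedom. Camera with an estimated correlation rests on these, so it could hardly call a list here and does not decide for or against them.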

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

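All tests reported in this part were chosen after the results were seen. A signal appeared in probes that the comparisons did not use: of 2788 detected probes with no gene name, 0 passed in the planned fit (limma, 93 at an unadjusted p below 0.05) and 48 passed with the neighbouring chip positions as a block, 40 higher and 8 lower with ACTH. ILMN_2391176 was higher by 3.87 and ILMN_2391178 by 3.72 on the log2 scale, with adjusted p = 8.73e-05 and 1.50e-05. ILMN_1713182 differed by -1.78 and ILMN_1764271 by -1.38, with adjusted p = 0.00131 and 0.00977. These probes were not matched to genes, and no explanation was tested.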

How the results depend on the processing

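The fit with the neighbouring chip positions as a block, its alternatives and the leaving out of whole pairs were chosen after seeing the data. The planned count of 0 genes held under every setting except 4. It was 2 without normalization between arrays (INHA and TMEM97, named after their values were seen, both at least 2-fold), 1 with the authors' processed values (INHA, 1 at least 2-fold), 191 with array weights (142 higher, 49 lower, 116 at least 2-fold, 8 of the 9 fixed genes), and 157 with the block (126 at least 2-fold, 7 of the 9). The weights were estimated without convergence and put 3.36 and 6.79 on replicate 3 of control and ACTH, against 0.313 to 0.618 on the others, so that count rests mainly on 2 arrays. The difference of TMEM97 lay between 0.66 and 3.05 on the log2 scale over the settings of the planned fit, so its size was not stable. The count of 14 lists stayed between 10 and 20 with camera at a preset correlation. It was 0 with an estimated correlation and 0 with fry, and with the block 16 became 0 and 0. Over the single lists, 250 values without the block kept the test's direction and call and 58 lost the call, and with the block 223 kept them and 49 lost the call. Directions of medians are a separate matter: without normalization that of the interferon list was 0.09 against -0.21, and with the block those of the actin and fibroblast lists were 0.13 and 0.11 against -0.15 and -0.17. With the block, single pairs decided the calls of the ACTH receptor list (adjusted p = 0.0846 without the second pair), the transcription regulators (0.0734 without the third), the interferon genes (0.112 without the third) and the zona glomerulosa genes (0.0529 without the first).

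With the block, the count of 157 became 253 without background correction, 244 with an offset of 50, 625 with median scaling (248 at least 2-fold), 755 without normalization (329), 28 without a filter on dim probes (28 at least 2-fold, 3 of the 9 fixed genes), 316 with an intensity trend and robust prior (3 of the 9), 348 with array weights and 331 with the authors' values. It was 39 at an adjusted p below 0.01 and 85 when tested against a 1.2-fold change. All 157 genes were among those called with median scaling, and 147 among those called without normalization. Leaving out 1 pair gave 6 to 381 genes, 6 to 290 at least 2-fold, and 3 to 9 of the fixed genes. With median scaling and without normalization the prior degrees of freedom were infinite, against 4.80, so those counts rest on 1 pooled variance. For the other changed counts the cause was not tested. The share of calls that were higher with ACTH was 75.8% with the block, 62.9% with median scaling, 90.9% without normalization and 62.3% with the trend. Without normalization the median of all genes moved from -0.02 to 0.27.

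SULT2A1, CHGB and TH, which passed in no setting, changed direction. SULT2A1 (-0.24) was 0.096 without normalization in both fits, 0.093 with array weights, 0.26 with the chip position as a covariate, -0.739 to 0.679 with 1 array left out and -0.472 to 0.214 with 1 pair left out. CHGB (-0.06) was 0.037 with median scaling, 0.276 without normalization and 0.0641 with the authors' values in both fits, 0.105 with array weights, -0.736 to 0.644 with 1 array left out and -0.190 to 0.0257 with 1 pair left out. TH (0.29) was -0.381 with the chip position as a covariate and -0.954 to 1.53 with 1 array left out, and with the block it kept its direction in all 15 settings (0.113 to 0.608). The cause was not tested. Signal over background limits the genes detected on part of the control arrays, such as MC2R, INHA, RDH12 and SEMA6D, whose control means lie close to the background.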

Other observations

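All tests in this part were chosen after the results were seen. The 3 pairs of neighbouring arrays differed from each other more in some gene lists than in others. The median SD between the pair means was 1.47 on the log2 scale for the 10 measured chromaffin markers (cells of the adrenal medulla that make catecholamines), 1.24 for 13 adrenocortical markers, 1.16 for 10 steroid synthesis enzymes, 1.13 for 13 fibroblast markers, 0.852 for 30 extracellular matrix genes and 0.712 for 8 metallothioneins, against 0.226 for all genes. The chromaffin markers CHGB and TH, named after their values were seen, had pair means of 10.7, 9.80 and 12.3, and of 9.05, 6.99 and 11.7. None of the 10 chromaffin genes is in another list, and 8 of the 13 fibroblast genes are. In contrast, the pairs differed little in markers of endothelial cells (0.282), adipocytes (0.265) and smooth muscle and pericytes (0.261), in ribosomal proteins (0.188) and in fatty acid synthesis and desaturation (0.193).

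The deviation of neighbouring arrays in the same direction was weighed against a trend along the chip and against different shares of chromaffin cells. The tables argue against a steady trend: the mean score of the middle pair on the first principal component (56.7% of the variance) lay 30.6 outside those of the outer pairs, with at most 13.4 between the arrays of a pair. Different shares of chromaffin cells may contribute, as a hypothesis: the median SD of 1.47 lay above all of 10000 random lists of like size and signal, whose median was 0.241. The chromaffin list had the largest spread of the 33 lists and was taken up after the results were seen. The comparison therefore restates that spread and is no separate support. The cortical and fibroblast markers varied nearly as much, and markers of endothelial cells, adipocytes and smooth muscle did not, so the value is not particular to chromaffin cells. Whether neighbouring arrays came from a shared culture stays open, since no label says so.

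The higher level of steroid synthesis genes with ACTH was weighed against a larger share of cortical cells and against scaling. A larger share as the sole cause predicts like differences within a pair only for cortical markers that the array reads in proportion. The variance between the 13 markers was 11.6 times the residual variance (permutation p = 0.0001, the smallest that 10000 permutations can give). The size of the difference was thus particular to the marker. But MC2R and INHA lay near background in control (5.68 and 5.51, detected on 2 of 3 arrays), and CYP11A1 reached 14.27 with ACTH. A single change of share could read differently in such markers, so the test over all 13 cannot by itself decide against it. But NR5A1, MRAP and HSD3B2 were alike and well above background in control replicate 1, at 10.63, 10.40 and 10.20. In that pair they differed by 0.30, 3.53 and 2.53. In the second pair they differed by 1.84, 4.62 and 4.50, and in the third by 1.49, 3.93 and 3.37. These values argue against a change of share as the sole cause for these markers. Scaling is argued against by the median of the list without normalization, 3.31, whose lower quartile was 1.38. A change in cortical share in addition to a change per cell stays open. That ACTH raised these genes in the cells is a hypothesis. The list was fixed in advance, but the checks on share and scaling were chosen after the results were seen, on the same 6 arrays.

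The lower level of cell cycle genes with ACTH was weighed against a smaller share of fibroblasts and against scaling. If fewer fibroblasts were the sole cause, their markers would have fallen as far, but the fibroblast median lay above the cell cycle median in all 3 pairs, by 0.274 to 0.411. The lists were not matched for signal level (for example DCN 13.88 and CENPF 8.45 in control), so this gap is limited evidence against a smaller share. Still, 12 of the 13 fibroblast markers were lower, so a part from fewer fibroblasts stays open. That list passed with the block (adjusted p = 0.0228) but not with an estimated correlation (0.400), without the first pair (0.0987), without the third (0.112) or with median scaling (0.130), and its median was 0.11 without normalization. Without normalization the cell cycle median was -0.18, and its upper quartile -0.08, while the median of all genes was 0.27.

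Chance was examined over other splits of the 6 arrays, which are too few for a share below 0.05. For the planned counts of genes, genes at least 2-fold and fixed genes, all 0, the 10 of 10 splits with as many follow from the 0 and say nothing about chance. The highest other counts were 5, 5 and 0. For lists 4 of the 10 gave at least 14, the real split included, with a highest other count of 19. Apart from the real one, these kept both arrays of a pair in the same group. The other splits that part all 3 pairs, as the real one does, gave 2, 4 and 4 lists without the block. With the block, 4 splits part all 3 pairs, and only the real one (1 split) gave 157 genes, 126 at least 2-fold, 16 lists and 7 fixed genes, where the highest others gave 0, 0, 7 and 0.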
